A study of Homo sapiens with 9 samples.

How the data were processed

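The data were 9 BrU-seq libraries from 3 RPE1 lines (WT, STK19 knockout and knockout with an STK19-TY transgene), each mock-treated or sampled 3 h and 16 h after 12 J/m2 of UV-C. Groups were taken from the sample titles. The labels differ on whether the pulse began or ended at 3 h and 16 h, and the start at 2.5 h and 15.5 h was taken. Per the labels' protocols, bromouridine-containing RNA was isolated from a 30 min pulse, and libraries were made with a TruSeq kit and sequenced as 151 bp paired-end reads on a NovaSeq. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.7a, HOMER 4.8.2, R 4.0.5 and the builds GRCh38 and hg38, with no role or order. Whether strand was used in counting is not given in the sources used here, so signal of overlapping and antisense transcription cannot be told apart from that of a gene. No spike-in is named in those sources.

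The deposited signal in the library files is coverage in 200-bp bins, in 1001 columns around each TSS, per the file headers. It had been scaled by the authors to a common total: 100% of values were whole multiples of a library's smallest step to within 0.02 of a step, and between 82.9% and 90.1% of isolated runs in a sample of identifiers filled 2 or 3 neighbouring bins, so the values were read as coverage and not as read counts. Steps ran from 0.373 in WT at 16 h to 4.88 in KO at 3 h, a 13.1-fold range of depth. A further 3 tables held the deposited signal averaged by the authors over 308, 787 and 1473 genes of at least 100, 50 and 25 kb. Their steps were between 3.73 and 43.1 times finer than those of the library files, so they were not computed from the deposited library rows, and how the authors chose the genes is not given beyond their length and level. Raw signal of the averaged tables was not set against raw signal of the library files, and comparisons of levels between libraries rest on the authors' scaling.

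The library files held 9805 identifiers, of which 7936 occurred in all 9 and were used. None of them matched the reference table given here, so gene names, gene ends, gene lists and STK19 were not analysed here. The level of a gene was therefore the mean signal per bin from 0 to 25 kb, which runs past the end of short genes and can include neighbours; the design fixed before the data were examined had asked for the gene body and for genes of 100 kb or more. In place of the latter, 279 long-span genes were chosen on the mean of the 9 libraries, after seeing the data: each of the 20 windows of 5 kb at 0.5 or more, no window at 6 times the median or more, and signal from 5 to 1 kb upstream under 0.5 times the median. Without gene ends, such a span may hold neighbouring genes too, so its near share need not describe position within a single gene. The near share was each gene's signal from 0 to 25 kb as a percentage of that from 0 to 100 kb, and intervals of its median came from 2000 bootstrap draws over genes.

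Tests were limma 3.58.1 (R 4.3.3, trend, empirical Bayes, Benjamini-Hochberg adjusted p under 0.05) on log2(level + 0.1) for 3602 identifiers with a mean level of at least 1, so that fold changes of low genes are understated. Count models were not used because the values are coverage. Near over far signal was tested as log2((near + 12.2)/(far + 12.2)), sums over bins, which replaces the logit of the design. The model held line and condition, leaving 4 residual degrees of freedom; the error was the part of the response that differed between lines. Responses particular to KO were tested with added KO-by-time terms, leaving 2 residual degrees of freedom, and assume that the KO libraries varied like those of WT and rescue. In tests of 3 h or 16 h against mock, the p-values measure the spread between lines, 2 of which derive from the same knockout, and not between repeated cultures. In tests between lines, the conditions stand in for repeats. Those p-values measure how constant a difference was over the conditions, and not the spread between clones or cultures. The ratio of the first 1 kb to the next 4 kb, with a pseudocount of 1 and a mean of at least 1 in both regions, was added after seeing the data.

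Genes named in the text were to be the 10 highest and 10 lowest by log2 fold change among those past the test, in the top 60 percent by level and moved the same way in every line; since no names were given, 2 identifiers that rose and 2 that fell at 3 h are named. The fits were tested on simulated data with the real means and residual spread, with 200 of 3602 identifiers or 60 of 279 long-span genes changed. At 3 h the test recovered 52 of 100 changed 2-fold and 98 of 100 changed 4-fold, with 6 false calls, and for the near share it recovered 17 of 30 and 29 of 30, with 3 false calls. Alternatives were the low-level filter, trimmed-mean scaling (factors between 0.817 and 1.19, in an implementation written for this purpose), the pseudocount, the level window, the block, each line or condition left out, and near windows of 10 and 50 kb. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.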

Results

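Nascent RNA was measured by BrU-seq in hTERT-immortalised RPE1 cells, a human retinal pigment epithelium line. In BrU-seq, cells take up bromouridine for a short pulse, and the RNA made during that pulse is pulled down with an antibody and sequenced. The 3 lines were the parental line with intact STK19 (WT), an STK19 knockout (KO) and the knockout carrying an STK19-TY transgene (rescue). Each line was either mock-treated or irradiated with 12 J/m2 of UV-C, and the 30 min pulse with 2 mM bromouridine began 2.5 h or 15.5 h after irradiation, so that labelling ended at 3 h or 16 h. UV-C leaves lesions in DNA that halt RNA polymerase II, and the series asks what STK19 contributes to the recovery of transcription afterwards. The design held 9 libraries, 1 for each line and condition. No difference between 2 libraries therefore had a replicate check, and tests across genes used the lines or the conditions as blocks.

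Each library file gave signal in 200-bp bins over 100 kb on either side of transcription start sites (TSS), for between 8499 identifiers (KO at 3 h) and 9520 identifiers (WT at 16 h). Values within a library were whole multiples of 1 smallest step, whose inverse gave the relative depth. The KO 3 h library was the shallowest. Against it, depth was 2-fold in rescue at 3 h, 2.59-fold in KO at 16 h, 3.59-fold in rescue mock, 3.61-fold in WT mock, 6.42-fold in WT at 3 h, 7.55-fold in KO mock, 8.82-fold in rescue at 16 h and 13.1-fold in WT at 16 h. The summed signal differed little between the 9 libraries despite that range of depth, so they had been scaled to similar totals. Values from the library files are therefore relative within a library, and a drop in total nascent RNA after UV would not appear in them. The total to which the authors' averaged profiles had been scaled is not known, so their ratios to mock were read along the gene and not as absolute output.

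At 3 h after UV, nascent RNA of long genes was concentrated near the TSS in all 3 lines. In the authors' averaged profile of 308 genes of 100 kb or more, the WT signal from 1 to 5 kb was 18.5 against 8.08 in mock, a ratio of 2.29, while the signal from 75 to 100 kb was 0.595 against 2.18, a ratio of 0.272. The KO reached ratios of 1.71 from 1 to 5 kb and 0.443 from 75 to 100 kb. The rescue line lay between them, at 1.93 and 0.329. In the same averages, the first 5-kb window below mock began at 15 kb in each line. Of the 20 windows between the TSS and 100 kb, 17 were below mock in each line, and both values depend on how the libraries were scaled. The share of the 0 to 100 kb signal that lay in the first 25 kb, called the near share here, went from 42.7% to 74.2% in WT, from 41.7% to 59.8% in KO and from 39.5% to 66.0% in rescue. In the library files, over 279 long-span genes with signal along the whole first 100 kb, the far loss was milder and the order of the lines was not kept, with ratios from 75 to 100 kb of 0.690 in WT, 0.620 in KO and 0.620 in rescue.

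At 16 h the lines parted. In the authors' averages of genes of 100 kb or more, the WT far signal was close to the mock value, with a ratio of 0.974 from 75 to 100 kb, and the middle of the genes lay above mock, at 3.39 against 1.82 from 25 to 50 kb (a ratio of 1.87), with the highest 5-kb ratio of 2.15 in the window that began at 30 kb. In KO the same regions stayed below mock, at 0.690 from 25 to 50 kb and 0.423 from 75 to 100 kb. Rescue was intermediate, at 0.819 and 0.576. Of the 20 windows, 4 were below mock in WT, 19 in KO and 18 in rescue. The lowest WT ratio was 0.802, in the window that began at 95 kb. These counts, and whether a region lay above or below mock, depend on how each library was scaled. The near share does not depend on that scale. The near share was 40.8% in WT, 1.90 points under its mock (a change of -1.90), 57.0% in KO, a change of 15.3 points, and 49.6% in rescue, a change of 10.1 points. The order of the lines in signal over mock was the same but the differences were smaller over the 279 long-span genes of the library files, at 1.201 in WT, 0.780 in KO and 0.929 in rescue from 25 to 50 kb, and 0.990, 0.683 and 0.784 from 75 to 100 kb.

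**Figure D1:**
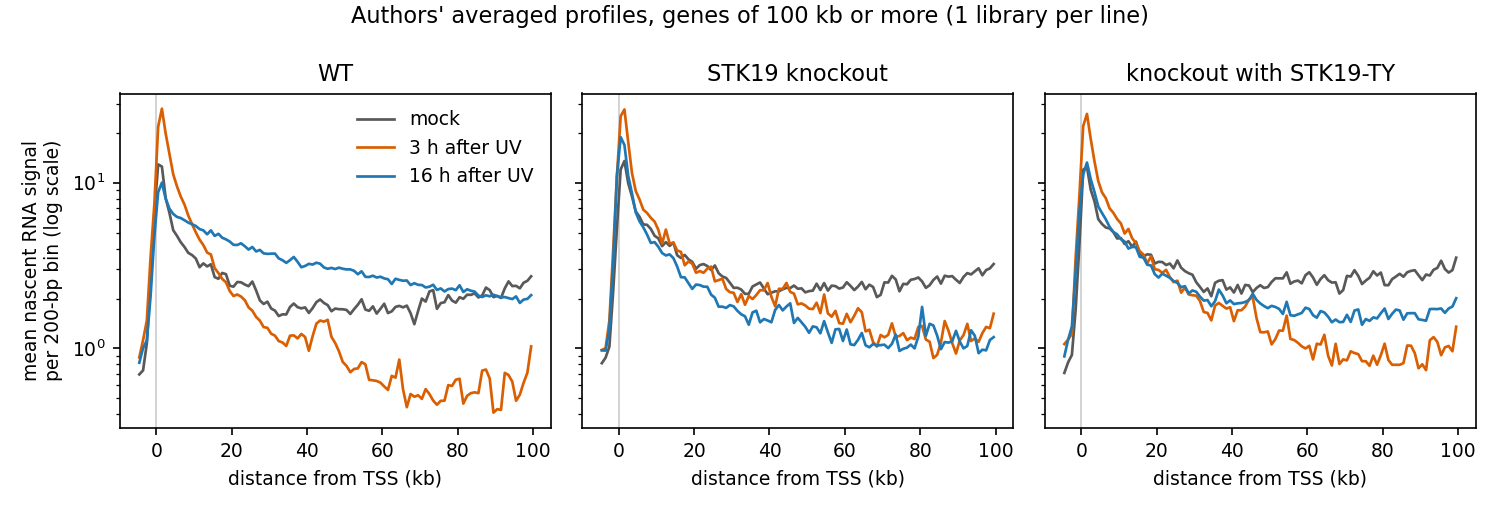
Authors' averaged nascent RNA signal per 200-bp bin (log axis) against distance from the TSS in kb, averaged here per 1 kb, for 308 genes of 100 kb or more; each panel is a line and each coloured curve 1 library (grey mock, orange 3 h, blue 16 h). Averaged over 75 to 100 kb, the 16 h signal in WT was 2.13 against 2.18 in mock, with a ratio of 0.802 in the 5-kb window from 95 kb. In KO it was 0.423 of mock.

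**Figure D2:**
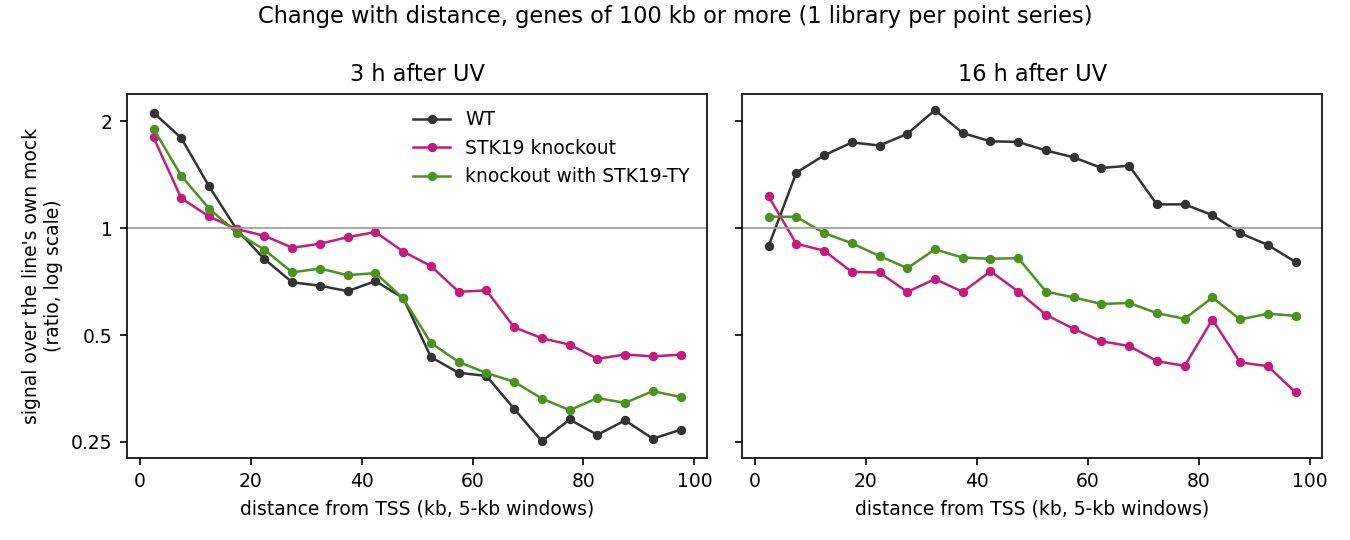
Signal after UV over the same line's mock (ratio, log axis) in 5-kb windows from the TSS to 100 kb, from the authors' averaged profile of genes of 100 kb or more; each curve is 1 line with 1 library per condition. At 3 h the curves cross 1 near 15 kb in every line, and at 16 h 4 WT windows lie under 1 against 19 in KO and 18 in rescue. The height of a curve, and so where it crosses 1, depends on the scaling of its libraries, while its shape does not.

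The order of the lines in near share was the same in the authors' averages of shorter genes, with smaller changes. Over 787 genes of 50 kb or more, the near share changed at 3 h by 25.8 points in WT, 13.8 in KO and 18.3 in rescue, and at 16 h by -1.22 points in WT, 10.3 in KO and 5.93 in rescue. Over 1473 genes of 25 kb or more, it changed at 3 h by 15.4 points in WT, 8.66 in KO and 11.1 in rescue, and at 16 h by -1.03, 6.63 and 3.69 points. The 16 h order depended on the 25 kb cut. In the same 1473 genes, the share of the first 50 kb went from mock to 16 h from 63.3% to 66.3% in WT. It went from 61.6% to 65.9% in KO and from 61.0% to 66.2% in rescue, which rose most. The WT signal between 25 and 50 kb at 16 h was above mock in these classes too, with ratios of 1.72 and 1.48, against 0.679 and 0.882 in KO and 0.957 and 1.11 in rescue. The 3 classes overlap, since a gene of 100 kb or more counts in each, and distances beyond 25 or 50 kb run past the ends of some genes in the shorter classes.

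The region next to the TSS differed between the lines as well. In the averages of genes of 100 kb or more, the first 1 kb stood at 18.8 in KO at 16 h against 12.0 in mock, a ratio of 1.57, while in WT it stood at 8.76 against 12.9, a ratio of 0.679, and in rescue at 11.2 against 12.0, a ratio of 0.937. The rescue ratio was above 1 elsewhere, at 1.08 and 1.14 for genes of at least 50 and 25 kb and 1.18 over the long-span genes. Set against the following 4 kb, the first 1 kb of genes of 25 kb or more had a ratio of 1.12 in KO mock, 1.40 at 3 h and 1.75 at 16 h. The same ratio was 1.47, 1.08 and 1.18 in WT and 1.23, 1.16 and 1.16 in rescue. Per gene, over 3053 identifiers with enough signal in both regions, the median log2 ratio was 0.02, 0.12 and 0.41 in KO at mock, 3 h and 16 h, 0.27, -0.11 and -0.02 in WT, and 0.14, 0.05 and -0.12 in rescue. No identifier passed limma's test for another 16 h change of this ratio in KO than in WT and rescue (adjusted p under 0.05), with 492 at an unadjusted p under 0.05 and a median log2 difference of 0.68. With the pseudocount 4 times higher, that median difference was 0.52.

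Single identifiers were followed through the 279 long-span genes, whose spans may include neighbouring genes since gene ends were not known. The median near share was 30.4% in WT mock, 51.1% at 3 h and 31.5% at 16 h. In KO it was 28.3%, 38.5% and 40.4%, and in rescue 27.7%, 40.8% and 33.9%. At 3 h the median had moved by 20.7 points in WT (95% bootstrap interval over genes 14.7 to 24.8), 10.2 in KO (8.07 to 13.3) and 13.1 in rescue (10.1 to 16.8). At 16 h it had moved by 1.10 points in WT, with an interval from -0.593 to 3.09, by 12.1 in KO (9.71 to 15.8) and by 6.18 in rescue (4.26 to 8.16). The near share was above its mock at 16 h in 149 of the 279 genes in WT, 211 in KO and 206 in rescue. Gene by gene, the 16 h change was larger in KO than in WT for 215 genes, by a median of 9.70 points, and larger in KO than in rescue for 179 genes, by a median of 4.04 points. These intervals describe the spread over genes within single libraries, not over repeated cultures. Restricted to the upper 140 genes by level, the changes were smaller, at 9.71, 4.77 and 5.17 points at 3 h and -1.57, 4.47 and 2.49 points at 16 h in WT, KO and rescue.

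**Figure D3:**
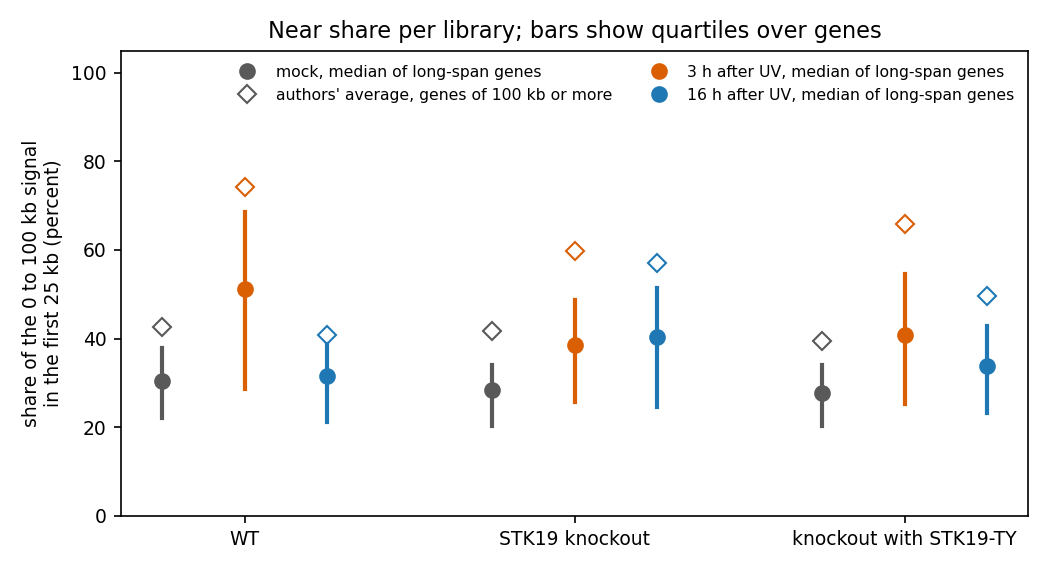
Share of the 0 to 100 kb signal lying in the first 25 kb (percent) per library, grouped by line; filled points are medians and bars quartiles over 279 long-span genes, and open diamonds the authors' averages of genes of 100 kb or more. WT medians go from 30.4% in mock to 51.1% at 3 h and 31.5% at 16 h, and KO medians from 28.3% to 38.5% and 40.4%.

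With the 3 lines as blocks, limma called 134 of the 279 long-span genes changed in near over far signal at 3 h, 126 towards the TSS and 8 away from it, with a median log2 change of 0.89 over all 279. Without the rescue line the count was 55. At 16 h 36 genes were called, 27 towards the TSS and 9 away, with a median of 0.43. This second count was 108 without the WT line, 18 without the KO line, 16 without the rescue line, 64 without the shallow KO 3 h library and 66 when only the mock and 16 h libraries were fitted. The test of another response in KO than in WT and rescue called 0 genes at 3 h (6 at an unadjusted p under 0.05) and 0 at 16 h (6 at an unadjusted p under 0.05), with medians of -0.22 and 0.48. That test rested on 2 residual degrees of freedom. On simulated data it recovered 8 of 30 genes changed 4-fold at 3 h and 18 of 30 at 16 h. Of genes changed 2-fold it recovered 3 of 30 at both times. The 2 contrasts had the same standard error for each gene, so the gap between 8 and 18 is no measure of unequal power.

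Levels within the first 25 kb were compared for 3602 identifiers. Between mock and 3 h, limma called 622 changed, 411 higher (66.1%) and 211 lower. Of these, 620 moved the same way in all 3 lines, against 62.0% of all 3602 identifiers. The test favours such agreement, since disagreement between lines is its error. The median log2 change over all identifiers was 0.22. With trimmed-mean scaling, which brought that median to 0.01, 205 were higher (40.2%) and 305 lower. With the level over 100 kb 154 were higher and 221 lower, and without a level filter 101 and 139, so the balance of directions depended on scaling, level window and filter. The count was 161 without the rescue line and 1357 when only the mock and 3 h libraries were fitted. The files pair no gene names with these identifiers. The 2 that fell most by the rule for named genes were uc062ihi.1, with levels of 26.9, 12.0 and 14.4 in WT, KO and rescue mock and 5.10, 2.23 and 1.82 at 3 h (log2 change -2.56, SE 0.29, adjusted p = 2.29e-06), and uc011lhk.3 (log2 change -2.28, SE 0.34, adjusted p = 6.4e-05). The 2 that rose most were uc059hwj.1, with levels of 3.49, 0.709 and 0.838 in mock and 50.6, 19.99 and 28.6 at 3 h (log2 change 4.46, SE 0.39, adjusted p = 8.32e-08), and uc002ouo.2 (log2 change 3.39, SE 0.35, adjusted p = 4.8e-07). All 4 moved the same way in each line, which the rule required. With the level over 100 kb the log2 change of uc059hwj.1 was 1.60. At 16 h uc059hwj.1 stood at 0.881 in WT, under its mock, and at 1.92 in KO and 1.54 in rescue, above theirs, whereas uc002ouo.2 stood at 1.99 in WT, 24.0 in KO and 11.03 in rescue, and uc062ihi.1 stayed at 4.32, 3.502 and 4.36.

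Between mock and 16 h, 1301 identifiers were called, 999 higher (76.8%) and 302 lower. Of these, 1264 moved the same way in all 3 lines, against 59.6% of all 3602, an agreement that the test again favours. The median log2 change over all was 0.42. With trimmed-mean scaling the median was 0.05, and 370 were higher (42.0%) and 511 lower. The count was 413 without the rescue line and 709 when the level was taken over the first 10 kb.

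KO and WT differed in 222 identifiers over the 3 conditions, 123 higher and 99 lower in KO, by limma with the conditions as blocks. The test asks how constant the difference was over the conditions, and the spread between clones was not measured. The count of 222 was not stable: 7 were called without a level filter, all lower in KO, 6 without the condition block and 50 over the first 10 kb. The count was 820 without the 16 h libraries, with 305 higher and 515 lower in KO and so the opposite balance, 61 without mock, 93 without the 3 h libraries and 133 when only the KO and WT libraries were fitted. Rescue and KO differed in 2 identifiers, both higher in rescue, with 47 at an unadjusted p under 0.05, and neither was among the 222. A separate response of KO was called for 0 identifiers at 3 h (43 at an unadjusted p under 0.05) and 0 at 16 h (277 at an unadjusted p under 0.05). On simulated data this test recovered 28 of 100 identifiers changed 4-fold at 3 h and 20 of 100 at 16 h, so a response confined to single genes was mostly not detectable with 1 library per line and condition.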

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

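The equal-depth and high-signal tests were set out before their results were seen; the tests of clone differences, of the share of genes behind the start-proximal signal and of other splits were chosen after, as were the long-span genes and the start-proximal ratio. With 1 library per line and condition, differences between lines were not tested against repeated cultures.

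The near share moved in opposite directions in KO and WT at 16 h in each of the authors' length classes: by 15.3 points in KO against -1.90 in WT for genes of 100 kb or more, 10.3 against -1.22 for 50 kb or more, and 6.63 against -1.03 for 25 kb or more. The opposite directions depended on the 25 kb cut. The share of the first 50 kb rose from mock to 16 h in both lines in each class. For genes of 100 kb or more it went from 60.7% to 65.5% in WT and from 60.3% to 74.9% in KO. For genes of 25 kb or more it went from 63.3% to 66.3% in WT and from 61.6% to 65.9% in KO. These differences between single libraries were not tested in the averages. The tests that follow cover the 279 long-span genes, where the WT median moved up by 1.10 points. With all libraries thinned to the depth of the shallowest, the KO change in the long-span median exceeded that of WT by 11.1 points (9.77 to 13.7 over 20 draws), against 10.98 without thinning. For these genes this argues against lower depth of the KO 16 h library as the cause. Each covered bin was drawn on its own, although isolated runs mostly fill 2 or 3 bins. Thinned libraries therefore kept more independent signal than truly shallow ones. The range over draws may be too narrow, and the value at equal depth may miss part of an effect of depth. With the 10 percent of genes of highest level left out, which held 37.6% of the signal, the pooled difference was 7.90 points against 7.51 with all 279 genes. This argues against a few genes of high signal in this set, and cannot decide the question for the authors' averages, which cover other genes. A difference between clones that has nothing to do with STK19 stays open: the rescue line lay 4.04 points under KO in the median gene, and no library of either line was repeated. A lasting lack of elongation into long genes without STK19 is a biological explanation that may hold, as a hypothesis not tested here that repeated cultures and another knockout clone would decide.

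At 3 h the near share of long-span genes rose more in WT than in either line derived from the knockout. At equal depth the WT change exceeded the mean of KO and rescue by 8.25 points (6.89 to 9.37 over 20 draws), against 9.10 without thinning, which argues against the low depth of the KO and rescue 3 h libraries. Bins were thinned in the same way, so this range may be too narrow too, and the value may again miss part of an effect of depth. The excess was smaller in the pooled signal, with changes of 11.8 points in WT, 8.08 in KO and 8.15 in rescue, and in the upper genes by level, with 9.71, 4.77 and 5.17. KO minus rescue was -2.37 points in the median gene, and WT minus rescue was 3.98. In the authors' averages of genes of 100 kb or more, rescue lay nearer to WT than to KO, with changes of 31.6 points in WT, 18.2 in KO and 26.5 in rescue. A difference between WT and the cells that KO and rescue derive from, whatever their STK19 state, cannot be told apart from an incomplete rescue, since each line has 1 library per condition.

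The ratio of the first 1 kb to the next 4 kb moved up in KO and down in WT after UV in every length class. In KO it changed at 3 h by 0.275, 0.245 and 0.285 for genes of at least 25, 50 and 100 kb, against -0.393, -0.438 and -0.420 in WT, and at 16 h by 0.627, 0.537 and 0.497, against -0.295, -0.388 and -0.483 in WT. Rescue moved down, by -0.0682, -0.177 and -0.226 at 16 h. Over 3053 identifiers of the library files, the KO change in the median log2 ratio at 16 h exceeded that of WT by 0.74 at equal depth. The value without thinning was 0.69, which argues against depth for these identifiers, within the same limits of the thinning. Of them, 79.6% had a larger change in KO than in the mean of WT and rescue, which argues against a few genes in this set. In the authors' averages the WT mock library had the highest ratio of the 3 mock libraries and the KO mock library the lowest, in every length class. For genes of 25 kb or more the ratios were 1.47 in WT mock, 1.12 in KO mock and 1.23 in rescue mock. Part of the contrast may come from the WT and KO mock libraries, a possibility the design leaves open.

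Signal from 5 to 1 kb upstream of the TSS, outside the measured gene bodies, stood in the authors' averages of genes of 100 kb or more at 1.41 times mock in WT, 1.49 in KO and 1.67 in rescue at 3 h, and at 1.002 in WT, 1.33 in KO and 1.51 in rescue at 16 h. The library files gave other values: over the 279 long-span genes 1.15, 0.924 and 1.31 at 3 h and 1.08, 1.55 and 1.66 at 16 h, and over 3602 identifiers 1.29, 1.24 and 1.42 at 3 h and 0.793, 1.25 and 1.18 at 16 h. These differences were not tested, and neither the direction in every library nor the order of the lines was kept between the sources.

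The splits of the 6 libraries of each comparison into 3 and 3 number 10, the real one included, too few for a share under 0.05. The line or condition block was kept in each split. A difference shared by the blocks therefore enters the error of the other splits and lowers their counts, so these counts are no measure of chance. Fitted on those 6 libraries alone, 3 h against mock gave 1357 identifiers and the highest other split 0; 16 h against mock gave 1237 and 5; KO against WT gave 133 and 3. In these 3 cases 1 of the 10 splits, the real one, gave as many. Rescue against KO gave 2, and 3 of the 10 splits gave at least as many; the highest, with 43, set KO mock, KO 16 h and rescue mock against the rest, which after blocking for condition compares KO with rescue at 16 h alone. For the near share, 3 h against mock gave 179 genes and the highest other split 0, and 16 h against mock gave 66 and 0, with 1 split as large in both.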

How the results depend on the processing

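The level over 0 to 100 kb, the restriction to steady signal and the omission of the KO 3 h library were chosen after seeing the data; the alternatives for annotated gene starts and for gene lists were not run, since no names or gene ends were at hand. Of 66 alternative counts whose main count was above 0, 34 lay within 1.5 times the main count, and of 48 alternative near-share changes 22 differed from the main value by less than 0.5 times the width of its bootstrap interval. In the library files, depth limits the KO 3 h library most. In the authors' averages the smallest steps ran from 0.08 in rescue at 16 h to 0.14 in KO at 16 h, with 0.113 in KO at 3 h. The cause of the changes below was not tested, except that a stricter filter tests fewer genes.

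Without a level filter the calls were 240 at 3 h (101 higher, 139 lower), 7 between KO and WT and 0 between rescue and KO. With a filter 4 times as strict they were 355 at 3 h, 769 at 16 h, 122 between KO and WT, 0 between rescue and KO and 1 for the 16 h response of KO, and 17 and 9 long-span genes at 3 h and 16 h. Without a block they were 304, 784, 6 and 0 for 3 h, 16 h, KO against WT and rescue against KO. With the level in the first 10 kb they were 709 at 16 h, 50 between KO and WT and 5 for the 3 h response of KO. With the level over 100 kb they were 375 at 3 h (154 higher, 221 lower) and 1 for the 16 h response of KO. Rescue against KO gave 0 with trimmed-mean scaling and 1 with the pseudocount at 0.025. The 16 h near-share count was 16 with a near window of 10 kb, 12 with steady signal and 64 without the KO 3 h library.

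Leaving out 1 line at a time gave 161 to 569 at 3 h, 413 to 1464 at 16 h, 55 to 146 long-span genes at 3 h and 16 to 108 at 16 h. Leaving out 1 condition gave 61 to 820 for KO against WT and 1 to 3 for rescue against KO.

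The near-share change at 3 h in WT, KO and rescue was 31.6, 18.2 and 26.5 points in the authors' profile, 30.7, 15.01 and 19.9 with steady signal and 9.71, 4.77 and 5.17 in the upper genes by level. It was 11.8 in WT and 8.15 in rescue when pooled, 15.5 in WT and 6.30 in KO with a near window of 10 kb and 14.02 in KO with 50 kb. At 16 h it was -1.90, 15.3 and 10.1 in the authors' profile and -1.57, 4.47 and 2.49 in the upper genes. With steady signal it was 16.7 in KO and 8.99 in rescue, and with a near window of 10 kb -1.20 in WT and 8.26 in KO. In WT it was 5.15 with a near window of 50 kb and 3.74 without the first 2 kb. The WT 16 h change, whose interval included 0, took either sign; the other 5 kept theirs in all alternatives.

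Of the 4 named identifiers, uc011lhk.3 lost its call without a level filter (adjusted p = 0.0763), with its log2 change of -2.28 unchanged, and the log2 change of uc059hwj.1 was 1.60 with the level over 100 kb against 4.46. The calls were kept in 47 of 48 alternatives.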

Other observations

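These values were computed after seeing the data. Rescue against WT, a comparison outside the plan, gave 295 identifiers past limma's test, 125 higher and 170 lower in rescue, against 222 between KO and WT and 2 between rescue and KO. Each pair of these comparisons shares the libraries of 1 line, so the counts are not independent of each other. None of these comparisons measures the spread between clones.

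At the level of all 3602 identifiers, the median log2 change at 3 h was 0.22 over the first 25 kb, 0.27 over the first 10 kb and 0.04 over 100 kb, and at 16 h it was 0.42, 0.41 and 0.29.

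In mock cells, in the authors' averages of genes of 100 kb or more, the signal from 25 to 50 kb was 1.82 in WT, 2.38 in KO and 2.47 in rescue. The WT 16 h value was 3.39. These are raw signals of single libraries that rest on the authors' scaling, and the differences were not tested.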
